A study of Mus musculus with 4 samples.

How the data were processed

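The data are single-cell RNA-seq counts of nestin-GFP-positive cells sorted by flow cytometry from the whole dentate gyrus of 8 male nestin-GFP mice, 4 infused with a miR-132 antagomir (2 µl at 0.33 nmol/ml, per the labels' protocols) and 4 with a scrambled oligonucleotide, whose dose is not given in the sources used here. Per the labels' protocols, 96 cells per mouse were sorted into plates, RNA was copied with oligo-dT primers by Smart-seq2, 100 pg of cDNA per cell went into Nextera XT libraries, and these were sequenced on a NextSeq500. Smart-seq2 has no molecular identifiers, so a count is a read and not a molecule, and Wilson intervals and folds against a floor of 3 counts cover counting error only. Oligo-dT priming captures polyadenylated transcripts, so the mature microRNA itself was not measured.

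The authors deposited raw counts of reads per gene symbol and well, 31557 symbols by 768 wells, with a second deposited table that gives the mouse, treatment, sort day and sequencing pool of each well. The submitters' processing notes name FastQC, STAR 2.5.2, Subread with featureCounts 1.5.1, Seurat 2.3.1 and build mm10. The annotation release, the strand setting and the limits used to keep cells are not given in the sources used here. Without strand, reads of a gene and of its antisense partner cannot be told apart, and reads shared between near-identical copies may have been split or dropped, which bears on ribosomal protein genes with their many pseudogenes. Counts were used as deposited, with no change of scale before the tests.

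Treatment and mouse came from the deposited well table. The 2 samples per treatment in the labels could not be tied to mice, so the mouse was the replicate. Counts were summed per mouse and never tested cell by cell. Mice 1, 3, 5 and 7 received the scrambled oligonucleotide and mice 2, 4, 6 and 8 the antagomir. Mice 1 to 4 were sorted on the first day and mice 5 to 8 on the second; pool L5 held mice 1, 2, 5 and 6 and pool L6 mice 3, 4, 7 and 8. Each combination of sort day and pool thus held 1 mouse of each treatment. Over the 12 pairs checked (4 in each of 3 comparisons), the correlation of the 2 mice's deviations from their group means ran from -0.01 to 0.15.

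Wells with under 500 (36 wells) or over 6000 detected genes (16 wells) were left out, which kept 716 wells with 4118 to 1640971 counts. The plan was to use the authors' limits; as these are not given in the sources used here, the limits were set after the number of genes per well had been seen. No doublet caller was run. Of the kept wells, 0 held at least 3 markers, at 10 counts or more, of 3 or more of 5 cell classes. A doublet would hold cells of fewer than 3 classes, so this count cannot tell whether doublets were among the kept wells. Kept cells were scaled to 10000 counts, logged and clustered with scanpy 1.11.5 (2000 variable genes, 20 principal components, 15 neighbours, Leiden resolution 1). Clusters were named only from marker genes fixed beforehand, with at least 3 markers detected in 25% or more of the cells. A cluster was left unnamed where its 10 leading genes held more markers of another type than of its own. Nacc2 was not among the variable genes used for clustering. Fold changes between clusters were used for names only.

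Tests between treatments used edgeR 4.0.16 in R 4.3.3 on summed counts, with filterByExpr, TMM scaling, the quasi-likelihood test and Benjamini-Hochberg adjustment within each comparison. Types with at least 10 cells in every mouse were tested, which were oligodendrocyte-like (at least 25 cells per mouse) and RGL or astrocyte-like cells (at least 15). A negative log2 difference means a lower level after the antagomir. A group in which a gene had no count was given a floor of 3 counts over the group. Precision was limited by the spread of the sums per mouse, in which differences between mice and the sampling of cells were not told apart. Among genes over 20 CPM the median half-width of the 95% interval of a log2 difference was 0.82 in all cells. It was 0.90 in oligodendrocyte-like and 1.67 in RGL or astrocyte-like cells. The code was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold in each comparison, which gave 3, 1 and 0 false calls. The changed genes were drawn from genes averaging over 20 CPM, so the recovery rates given below do not cover genes under that level.

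Gene lists were 24 sets of textbook genes and markers of other cell types. They were tested with camera of limma 3.58.1 (preset correlation 0.01, log2 CPM with a prior count of 2, at least 5 tested genes), with camera with an estimated correlation, and with fry. Adjustment was over lists within a comparison. Seed matches were searched in the longest 3' UTR of each gene in GENCODE M21 (GRCm38), and the same statistic was computed for 100 reordered motifs. The difference in response between 2 cell types was tested in edgeR with the mouse as a block. Shares of cells were compared by exact two-sided permutation over mice, and shares between cell types by exact sign-flip tests over the 8 mice.

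The tests, the gene lists, the cell type markers and the rule for named genes were fixed before the data were examined. That rule names up to 10 genes in each direction past the threshold, fills a direction with fewer than 5 up to 5 genes with the smallest p, always names Nacc2, and takes up to 4 members with the smallest p from each list discussed. Which lists were discussed member by member was decided after the list results were seen. The targets compared between cell types, and the comparison by pool, were also chosen after the data had been examined.

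Alternatives fixed beforehand were DESeq2's size factors, DESeq2 1.42.0, no filter, a filter of 10 counts in every mouse, limma on mean log2(CPM + 1) over cells, cells with at least 1000 genes, a minimum of 20 cells per mouse, Leiden resolution 0.5, leaving out each mouse in turn, an estimated correlation, fry, 8-base seed matches and matching on 3' UTR length and expression. Added after the data had been seen were sort day and pool as a block, pool as a covariate, counts without mitochondrial and Rn18s-rs5 reads, all wells, RGL or astrocyte-like cells with the unnamed cluster, shares with the wells under 500 genes counted, the endothelial-like and mural-like cells and the wells over 6000 genes. Other computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.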

Results

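Nestin-GFP-positive niche cells were sorted from the dentate gyrus of 8 male reporter mice. The dentate gyrus is the part of the hippocampus in which neurons are still born in the adult, and nestin marks its neural stem cells as well as some vascular and glial cells. In 4 mice an antagomir against miR-132, a microRNA induced by neuronal activity, had been infused into the cerebral ventricle. The antagomir is a cholesterol-modified oligonucleotide of locked nucleic acids meant to block the microRNA. Mature miR-132 was not measured, so its block in these cells is not known from these data. The other 4 mice had received a scrambled oligonucleotide. Injection was at 2 months of age and analysis at 3 months. Each mouse gave 96 wells of Smart-seq2 read counts, and 716 wells with 500 to 6000 detected genes were kept, 353 from antagomir and 363 from scrambled mice. A kept well held a median of 650777 counts and 2778.5 detected genes. Counts summed over the kept wells of a mouse ranged from 43996495 to 69191485. The mouse was the replicate throughout (n = 4 per treatment). Each of 2 sort days and each of 2 sequencing pools held 2 mice of each treatment.

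Oligodendrocyte-like cells were the most numerous of the named types, with 301 of 716 cells (42.0%, Wilson 95% interval 38.5% to 45.7%). Genes of the myelin sheath and of mature oligodendrocytes were among those leading 2 of their 3 clusters, Ermn, Mal and Opalin in 1 and Klk6 in the other, and the myelin gene Mag was among those leading the remaining cluster. Radial glia-like (RGL) or astrocyte-like cells numbered 155 (21.6%), and their main cluster was led by Gja1, the astrocyte gap junction protein, and by Atp13a4, F3 and Grin2c. A smaller cluster of 23 cells in this class had counts of Nes, the filament gene that drives the reporter, in 100% of its cells. It had counts of Hopx, a gene of quiescent stem cells, in 78.3%. Endothelial-like cells numbered 87, led by Cldn5 and Flt1. Mural-like cells numbered 84, led in their larger cluster by the contractile genes Acta2 and Myh11. Neuroblast-like cells numbered 36, led by Sox11, Neurod1 and Calb2, and 75% of them had counts of Dcx, a microtubule protein of migrating neuroblasts. Fibroblast-like cells numbered 12 and oligodendrocyte precursor-like cells 5. A cluster of 36 cells with a median of 820 detected genes and 11.6% mitochondrial counts, led by Camk2a, was left unnamed. It had 13 of the RGL or astrocyte markers in 25% or more of its cells. Its 10 leading genes held 0 of these markers and 1 of neurons, which kept it from that name. The immediate early gene Arc was among the leading genes of 1 oligodendrocyte-like cluster, the microglial gene Ctss of another, and the stress genes Socs3 and Hspa1a of the smaller mural-like cluster. The oligodendrocyte-like clusters also differed in pool. Pool L6 gave 93.4% of the cells of the cluster with Ermn, 25.6% of that with Klk6 and 11.5% of the remaining one.

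Nacc2, a transcriptional repressor with a BTB domain that the series title names as an effector of miR-132, was detected in 292 of the 716 cells (40.8%). Over the 8 mice it was detected in 56.9% ± 11.5 (SD, n = 8) of oligodendrocyte-like cells and in 58.5% ± 8.39 of RGL or astrocyte-like cells. The share was 8.17% ± 11.3 in endothelial-like, 10.8% ± 12.8 in mural-like and 2.08% ± 5.89 in neuroblast-like cells. In each of the 8 mice oligodendrocyte-like and RGL or astrocyte-like cells both had a higher share than each of these 3 types (exact two-sided sign-flip p = 0.00781, adjusted over 10 pairs of types p = 0.0130; 0.00781 is the smallest p that 8 mice allow). The 2 glial classes did not differ from one another beyond the spread between mice, with a difference of -1.54 percentage points (exact p = 0.742). Nacc2 was detected in 0 of 12 fibroblast-like cells, for which the Wilson upper limit was 24.2%, in 3 of 5 oligodendrocyte precursor-like cells (60.0%, Wilson interval 23.1% to 88.2%) and in 6 of 36 unnamed cells (16.7%). The median depth was 830052 counts in oligodendrocyte-like, 599721 in RGL or astrocyte-like, 565180 in endothelial-like, 521570.5 in mural-like and 590843 in neuroblast-like cells. After thinning every cell to 200000 counts the shares were 57.3%, 58.5%, 10.3%, 9.21% and 3.03%, with 6, 13, 9, 8 and 3 shallower cells left out.

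Nacc2 lies on the minus strand of chromosome 2 between bases 26055535 and 26123220 of mouse build GRCm38. The longest annotated 3' UTR of the gene has 4427 bases and 2 copies of the 8-base miR-132 seed match GACTGTTA, at bases 26055960 to 26055967 and 26055757 to 26055764. Among 24 targets of miR-132 reported in the literature, chosen without these data, 22 had at least 1 seed match of 7 bases in the longest 3' UTR.

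**Figure D1:**
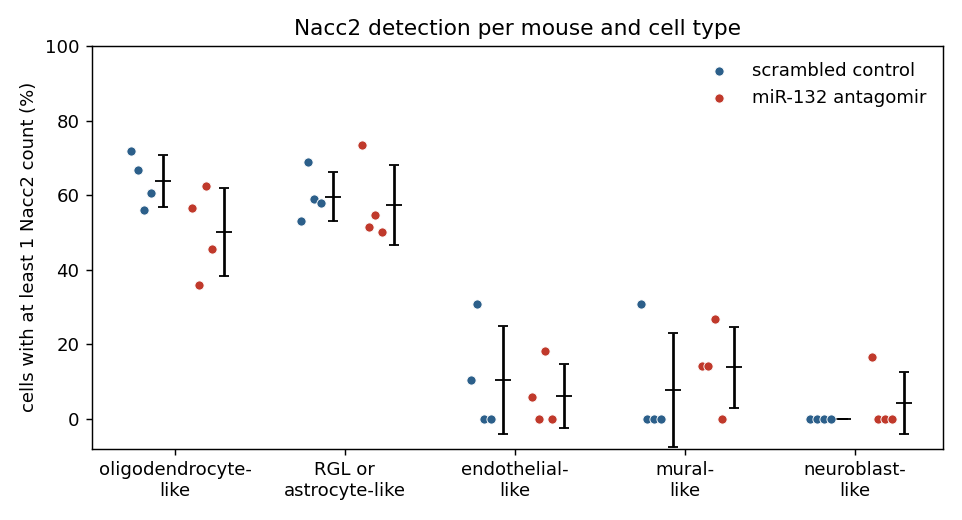
Percentage of cells with at least 1 Nacc2 count in each mouse, by cell type and treatment. Each point is a mouse and the black bar with whiskers is the mean ± SD over 4 mice; oligodendrocyte-like and RGL or astrocyte-like cells averaged 56.9% and 58.5%, the other 3 types shown 10.8% or less.

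Of 19 reported targets compared between the 2 largest classes, 7 differed, 3 higher in oligodendrocyte-like and 4 in RGL or astrocyte-like cells. CPM are counts scaled to the total of the cells summed, here those of the cell type in the mouse. Mapt, which encodes the microtubule protein tau, averaged 1344 ± 103 CPM in oligodendrocyte-like and 159 ± 71.4 in RGL or astrocyte-like cells (SD, n = 8). Zeb2, a transcription factor needed for myelination, averaged 450 ± 67.7 against 79.2 ± 48.6, and Paip2, an inhibitor of translation, 343 ± 67.9 against 194 ± 57.0. Arhgap32 was higher in RGL or astrocyte-like cells with 135 ± 57.2 against 27.1 ± 19.2 CPM, as were Rb1, the retinoblastoma repressor of the cell cycle, with 44.6 ± 10.9 against 8.54 ± 11.4, and Itpkb, an inositol trisphosphate kinase, with 30.9 ± 29.5 against 0.00813 ± 0.0155. These 6 genes were ordered alike in 8 of 8 mice (exact sign-flip p = 0.00781, adjusted over 19 targets p = 0.0247). Foxo1, a transcription factor of the insulin pathway, was higher in RGL or astrocyte-like cells in 7 of 8 mice (63.2 ± 18.3 against 12.5 ± 9.68 CPM; exact p = 0.0156, adjusted p = 0.0424). The remaining 12 targets compared did not pass, among them Nacc2 with a mean log2 difference of 0.11 (SD 0.74, n = 8; exact p = 0.727).

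The first comparison asked whether the antagomir changed the level of Nacc2. In all cells of a mouse together Nacc2 was at 105 ± 35.7 CPM after the antagomir and 119 ± 16.9 after the scrambled control (SD, n = 4 each). In oligodendrocyte-like cells it was at 119 ± 56.0 and 162 ± 24.2 CPM, and in RGL or astrocyte-like cells at 155 ± 64.0 and 143 ± 32.8. None of these differences exceeded the spread between mice by edgeR's quasi-likelihood test. By edgeR the log2 difference, antagomir minus scrambled, was -0.21 in all cells (SE 0.26, 95% interval -0.79 to 0.37), -0.46 in oligodendrocyte-like cells (SE 0.34, interval -1.22 to 0.29) and 0.15 in RGL or astrocyte-like cells (SE 0.38, interval -0.69 to 0.99), and all 3 adjusted p-values were 1.00. The share of oligodendrocyte-like cells with Nacc2 counts was 50.1% ± 11.7 after the antagomir and 63.8% ± 6.93 after the control (exact permutation p = 0.143). It was 57.3% ± 10.8 and 59.6% ± 6.62 in RGL or astrocyte-like cells (exact permutation p = 0.657). Within pool L5 the log2 differences in all, oligodendrocyte-like and RGL or astrocyte-like cells were 0.25, -0.10 and 0.35, and within pool L6 they were -0.73, -1.07 and -0.01, of which the second had an unadjusted edgeR p of 0.0125. Within the first sort day they were -0.48, -0.80 and -0.09, and within the second 0.01, -0.13 and 0.38. In RGL or astrocyte-like cells the difference turned to -0.11 without mouse 8. By limma on mean log2(CPM + 1) over cells the differences in all, oligodendrocyte-like and RGL or astrocyte-like cells were -0.33, -1.26 and 0.21. The second had an unadjusted limma p of 0.0234 and an adjusted p of 0.999.

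**Figure D2:**
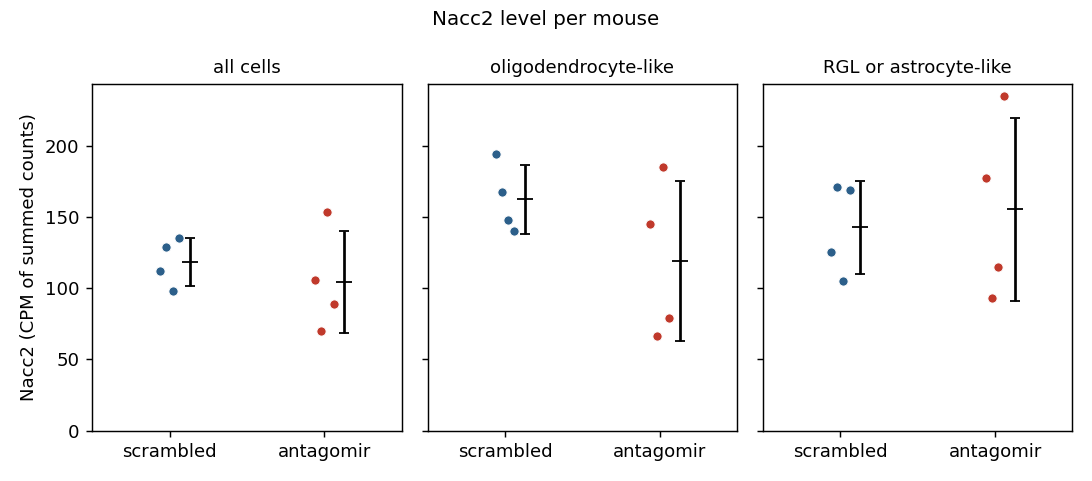
Nacc2 level in CPM of the counts summed over the cells of a mouse, for all cells, oligodendrocyte-like cells and RGL or astrocyte-like cells. Each point is a mouse and the black bar with whiskers is the mean ± SD over 4 mice; the treatments overlap in every panel, with means of 105 and 119 CPM in all cells.

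In all cells no gene passed by edgeR, so the genes with its smallest p in each direction are described with their values. Pdlim4, which binds actin fibres, was at 65.4 ± 23.3 CPM after the antagomir and 18.7 ± 5.61 after the control, and Irak1, a kinase of Toll-like and interleukin-1 receptor signalling, at 25.8 ± 6.65 and 4.61 ± 3.8 (SD, n = 4 each). Mogat1, an enzyme of diacylglycerol synthesis, had counts in 9 antagomir cells and 0 control cells. Against a floor of 3 counts over the group it was 76.9-fold higher. Hyal3, of the hyaluronidase family, had counts in 4 and 0 cells, 298-fold higher against that floor. Ssc4d, a scavenger receptor protein, was at 1.73 ± 2.21 and 0.0128 ± 0.00897 CPM (counts in 7 and 3 cells). In the other direction Hsf5, of the heat shock factor family, was at 0.0180 ± 0.00332 and 1.38 ± 0.148 CPM (4 and 10 cells), and Parp10, an ADP-ribosyltransferase, had counts in 1 antagomir and 13 control cells. Tmsb15b2, a thymosin, Pstpip1, a cytoskeletal adaptor, and Ripk4, a kinase of epidermal differentiation, had counts in 0 antagomir cells and in 8, 6 and 5 control cells. Against the floor they were 19.1-fold, 162-fold and 360-fold lower. Most of these genes rested on counts in few cells, and the folds cover counting error only.

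By edgeR's quasi-likelihood test 0 of 15447 genes passed an adjusted p of 0.05 in all cells, with 280 at an unadjusted p under 0.05, 148 of them higher. DESeq2's Wald test called 10 genes, 3 higher and 7 lower, Pdlim4, Hyal3, Parp10, Pstpip1 and Ripk4 among them, and limma on mean log2 values called 0, with 109 higher and 313 lower at an unadjusted p under 0.05. In simulated data with these means and depths edgeR recovered 59% of genes changed 4-fold and 3% of genes changed 2-fold. The changed genes all averaged over 20 CPM, so most changes of 2-fold would have been missed even at that level. Recovery of genes under 20 CPM was not simulated.

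Myelin genes passed as a list by 1 of 3 list tests when all cells were pooled per mouse. All 18 tested members of the list of myelin and oligodendrocyte maturation genes had a negative log2 difference, with a median of -0.27, and the list fell by camera with a preset correlation (adjusted p = 0.00331) but did not pass with an estimated correlation (0.868) or by fry (0.925). Named members were Ugt8a and Fa2h, enzymes of the myelin lipids galactosylceramide and hydroxylated sphingolipid, at -0.36 and -0.40, Mog, a protein of the outer myelin surface, at -0.29, and Enpp6, a choline phosphodiesterase of newly formed oligodendrocytes, at -1.05. None of these members passed the test per gene, and 0 of 18 passed when adjusted over the list alone. The preset call was lost without mouse 3, 4, 6 or 7 (adjusted p = 0.0529, 0.205, 0.0582 and 0.0667). The share of oligodendrocyte-like cells was 39.9% in antagomir and 44.5% in control mice, and within these cells the list's median was -0.09 (camera adjusted p = 0.153).

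Genes of quiescence, proliferation and neuronal differentiation and the reported targets did not pass as lists in all cells. Genes of neural stem cell quiescence had a median log2 difference of 0.10, with Id3, a BMP-responsive inhibitor of differentiation, at 0.62, Apoe, the lipid carrier, at 0.34, Hes5, a Notch effector, at 0.70 and Sox2, the stem cell factor, at 0.67, which turned to -0.31 without mouse 4. Proliferation genes had a median of -0.14, with Mcm4, a subunit of the replicative helicase, at -0.65, the cyclins Ccne2 and Ccne1 at -1.80 and 1.83, the latter turning to -1.36 with pool as a covariate, and Nusap1, a spindle protein, at 3.21; Ccne2, Ccne1 and Nusap1 had counts in at most 18 cells per treatment. Genes of neuronal differentiation had a median of -0.20, with Elavl4, a neuronal RNA-binding protein, at 1.04, Tbr1, a factor of glutamatergic neurons, at -3.24 (4 and 6 cells), and Tubb3 and Dpysl3, cytoskeletal proteins of young neurons, at -0.42 and -0.49. The reported miR-132 targets had a median of -0.01, with Foxo1 at 0.58, Kdm5a, a histone demethylase, at 0.46, Ep300, a histone acetyltransferase, at -0.37 and Zeb2 at -0.28. None of these genes or lists passed (camera adjusted p = 0.506, 0.422, 0.380 and 0.422; 0 genes of each when adjusted over the list alone).

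Of the other lists in all cells, medians were 0.11 for astrocyte function, 0.14 for astrocyte reactivity, 0.16 for disease-associated microglia, 0.42 for homeostatic microglia and 0.15 for the interferon response. They were 0.14 for blood-brain barrier endothelium, -0.21 for mural cells and vascular matrix, -0.06 for oligodendrocyte precursors and -0.11 for mature neuron transcripts. Oxidative phosphorylation, ribosomal proteins and cholesterol biosynthesis had medians of 0.08, 0.03 and 0.06, Notch, Wnt and BMP or TGF-beta signalling -0.14, -0.15 and -0.07, and Alzheimer risk genes -0.11. Dissociation and immediate early genes were at -0.08 and microglial inflammation at -0.53. Camera's adjusted p-values for these lists lay between 0.380 and 0.789, and the 1 list of blood cell transcripts had under 5 tested genes in every comparison. The median and the mean differed in sign for the reported targets, proliferation, immediate early genes, oligodendrocyte precursors, BMP or TGF-beta signalling and mature neuron transcripts.

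In oligodendrocyte-like cells B2m, the light chain of MHC class I, was at 183 ± 91.7 CPM after the antagomir and 59.0 ± 28.2 after the control (SD, n = 4 each; log2 difference 1.64, SE 0.41). Pla2g6, a calcium-independent phospholipase, was at 34.5 ± 20.2 and 4.66 ± 2.95 CPM, Phf5a, a splicing factor subunit, at 160 ± 10.7 and 97.7 ± 13.3, and Surf1, an assembly factor of cytochrome c oxidase, at 149 ± 14 and 92.1 ± 15.8. Ubxn11 had counts in 7 antagomir cells and 1 control cell. Cep68, a centrosome protein, was at 0.518 ± 0.637 and 28.4 ± 17.2 CPM (counts in 4 and 25 cells), and Hsf5 at 0.0143 ± 0.0286 and 2.27 ± 0.835 (1 and 7 cells). Zbtb33, which binds methylated DNA, Zfp39, a zinc finger gene, and Tmem169, a membrane protein, had counts in 0 antagomir cells and in 7, 10 and 5 control cells. Against the floor of 3 counts they were 160-fold, 287-fold and 155-fold lower. These folds cover counting error only and set no limit on the difference between mice. None of these genes passed by edgeR, where 0 of 10786 genes reached an adjusted p of 0.05, with 89 higher and 121 lower at an unadjusted p under 0.05. DESeq2's Wald test called 14 genes, 3 higher and 11 lower, with B2m, Pla2g6, Ubxn11, Tmem169, Zbtb33, Zfp39 and Cep68 among them, and limma on mean log2 values called 0, with 101 higher and 353 lower at an unadjusted p under 0.05. Among genes over 20 CPM, simulated 4-fold changes were recovered for 43% and 2-fold changes for 2%.

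Genes of oxidative phosphorylation and of the cytosolic ribosome passed as lists by 1 of 3 list tests in oligodendrocyte-like cells. Of the 34 oxidative phosphorylation genes 29 had a positive log2 difference, with a median of 0.15, and the list rose by camera with a preset correlation (adjusted p = 0.00110) but did not pass with an estimated correlation (0.510) or by fry (0.502). Atp5c1 and Atp5o, subunits of ATP synthase, were at 0.47 and 0.40, Ndufb3, of complex I, at 0.48 and Sdhb, of complex II, at 0.39. Of the 35 ribosomal protein genes 30 were positive, with a median of 0.15, and this list rose by the preset correlation as well (adjusted p = 0.00188) but not by the other tests (0.510 and 0.502). Its members Rpl10, Rpl14, Rps14 and Rps9 were at 0.34, 0.35, 0.21 and 0.22. No member of either list passed the test per gene, and 0 passed when adjusted over the list alone. The preset call was lost without mouse 8 for oxidative phosphorylation (adjusted p = 0.0529) and without mouse 4 for ribosomal proteins (adjusted p = 0.0721).

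**Figure D3:**
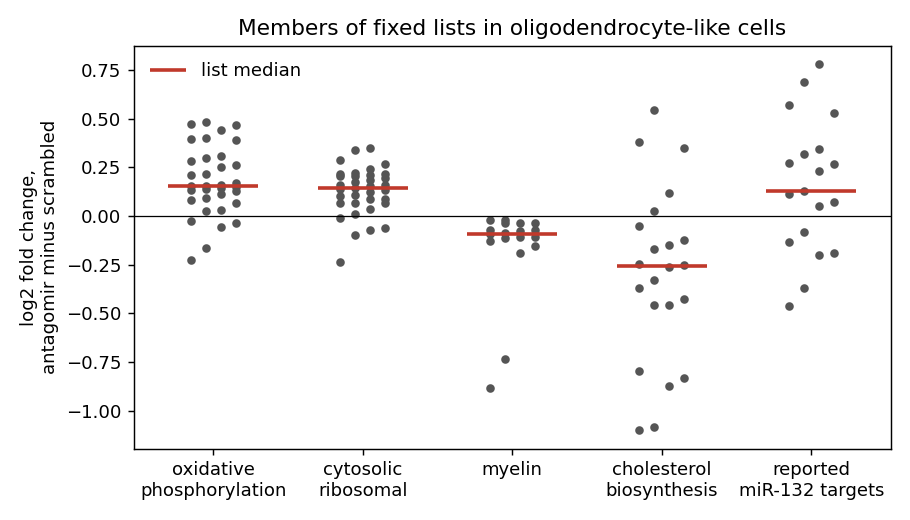
Log2 difference, antagomir minus scrambled, of each tested gene of 5 gene lists in oligodendrocyte-like cells. Each point is a gene and the red line is the list's median, which is 0.15 for oxidative phosphorylation and for ribosomal proteins and -0.09 for myelin genes.

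Other lists in oligodendrocyte-like cells did not pass by camera. All 18 myelin genes were negative, with a median of -0.09 (adjusted p = 0.153); Tcf7l2, a Wnt effector in differentiating oligodendrocytes, was at -0.73, Enpp6 at -0.88, Ugt8a at -0.16 and Fa2h at -0.19. Of 11 tested genes of disease-associated microglia 9 were positive, with a median of 0.06 (camera adjusted p = 0.0813). Fry, which tests whether the genes of a list move one way on balance, called this list (adjusted p = 0.0263). That call was lost with sort day and pool as a block (0.433) and without any mouse but mouse 2 (0.0605 to 0.559). B2m was the 1 member that passed when adjusted over the list alone. Besides B2m, the lysosomal protease Ctsd was at 0.26, the lysosomal membrane protein Cd63 at 0.15, which turned to -0.23 by limma on mean log2 values, and Lpl, a lipase, at -0.55, which turned to 0.22 with sort day and pool as a block. The reported targets of miR-132 had 13 of 19 positive genes and a median of 0.13, against a camera direction of lower (adjusted p = 0.920), with Foxo3, a stress-responsive transcription factor, at 0.57, Kdm5a at -0.37 and Paip2 at -0.19. Medians were -0.26 for cholesterol biosynthesis (17 of 22 negative), -0.97 for oligodendrocyte precursors, -0.15 for astrocyte function, 0.10 for astrocyte reactivity, -0.60 for blood-brain barrier endothelium and 0.48 for the interferon response, with camera adjusted p-values of 0.149, 0.166, 0.0959, 0.0959, 0.0959 and 0.144. The remaining lists had adjusted p-values from 0.388 to 0.920.

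In RGL or astrocyte-like cells the smallest p belonged to Dedd2, a death effector domain protein, with counts in 2 antagomir and 8 control cells and 0.0365 ± 0.0482 against 56.2 ± 42.7 CPM (SD, n = 4 each; edgeR adjusted p = 0.260). Nqo1, a quinone reductase of the oxidative stress response, was at 37.0 ± 9.06 CPM after the antagomir and 0.0920 ± 0.127 after the control (counts in 9 and 2 cells), and Suox, the mitochondrial sulfite oxidase, at 95.8 ± 14.7 and 12.1 ± 9.29. Hipk2, a kinase of the p53 and Wnt pathways, was at 231 ± 61.5 and 91.9 ± 27.4, and Hbegf, a ligand of the EGF receptor, at 206 ± 78.4 and 70.2 ± 29.6. Celf3, an RNA-binding protein of neurons, had counts in 5 and 0 cells, 64.6-fold higher against the floor of 3 counts. Sh3d19 and Arhgef37 had counts in 0 antagomir cells and in 6 control cells each, 151-fold and 191-fold lower against it. The folds against the floor cover counting error only and set no limit on the difference between mice. P4ha3, a collagen hydroxylase, had counts in 3 and 7 cells and Ntng2, a netrin-like adhesion protein, in 1 and 4. By edgeR 0 of 10726 genes passed, with 68 higher and 69 lower at an unadjusted p under 0.05. DESeq2's Wald test called 7 genes, 3 higher and 4 lower, with Nqo1, Suox, Dedd2, P4ha3 and Arhgef37 among them, and limma on mean log2 values called 0, with 82 higher and 612 lower at an unadjusted p under 0.05. Fewer cells entered the sums here, and among genes over 20 CPM simulated 4-fold changes were recovered for 5% and 2-fold changes for 0%.

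Proliferation genes had the largest negative median of the lists in RGL or astrocyte-like cells. It was -1.21 over 12 tested genes, of which 9 were negative, and the list did not pass (camera adjusted p = 0.135; 0.887 with an estimated correlation). Tubb5, a tubulin of dividing cells, was at 168 ± 45.8 CPM after the antagomir and 364 ± 265 after the control, Hmgb2, a chromatin protein of cycling cells, at 9.16 ± 6.41 and 36.9 ± 24.2, and Mcm2 and Mcm7, of the replicative helicase, at 2.82 ± 3.88 and 20 ± 15.3 and at 13.5 ± 17.8 and 49.5 ± 51.9. Hmgb2, Mcm2 and Mcm7 had counts in 9, 2 and 7 antagomir and 15, 4 and 13 control cells. Of the 25 quiescence genes 20 were negative, with a median of -0.15 (adjusted p = 0.697); Apoe was at 0.28, Fabp7, the fatty acid-binding protein of radial glia, at -0.55, Gfap, the astrocyte filament, at -0.41 (-0.67 to -0.03 without a mouse) and Slc1a3, a glutamate transporter, at -0.16 (-0.25 to -0.02). Genes of neuronal differentiation had a median of -0.24 over 10 genes (adjusted p = 0.682), with Sox4 and Sox11, factors of neuronal commitment, at -4.07 and -3.05, Dpysl3 at -3.81 and Elavl4 at 3.77, each from at most 9 cells per treatment. The 22 genes of astrocyte function were split 11 to 11, with a median of 0.01 (adjusted p = 0.902); Aldh1l1, a folate enzyme, was at -0.41, Mlc1, a membrane protein of end-feet, at -0.30, the GABA transporter Slc6a11 at -0.43 and the amino acid transporter Slc7a10 at 0.34. The reported targets had a median of -0.23 over 18 genes (adjusted p = 0.682), with Ache, acetylcholinesterase, at -5.71 (counts in 2 antagomir and 6 control cells), Rasa1, a Ras inhibitor, at -2.21 (9 and 14 cells), Arhgap32 at -0.60 and Zeb2 at 0.70. No gene of these 5 lists passed when adjusted over the list alone.

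Other medians in these cells were -0.45 for astrocyte reactivity, -0.44 for dissociation and immediate early genes, -0.96 for mural cells and vascular matrix, -0.34 for the interferon response and 0.03 for oxidative phosphorylation. Ribosomal proteins were at -0.04, cholesterol biosynthesis at 0.12, Alzheimer risk genes at 0.06 and Notch, Wnt and BMP or TGF-beta signalling at -0.18, -0.15 and -0.15. Camera's adjusted p-values for lists not given above lay between 0.257 and 0.929.

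The effect of the antagomir was compared between RGL or astrocyte-like and oligodendrocyte-like cells of the same mice. With the mouse as a block, 0 of 13322 genes differed in their response by edgeR, with 261 at an unadjusted p under 0.05. No other tool was run for this test. The response of Nacc2 differed by 0.70 on the log2 scale (SE 0.55, 95% interval -0.54 to 1.94, unadjusted p = 0.238), so a difference between the 2 types was not detectable.

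A microRNA represses transcripts that carry its seed match, and a shift of such transcripts after the antagomir was tested over all genes with a 3' UTR. Of 20657 genes with a 3' UTR of at least 50 bases, 2251 had a match of 7 bases to the miR-132 seed and 495 a match of 8. In all cells the 1671 tested genes with a match had a z of -0.50 by limma's camera against other genes, and 59 of 100 control motifs with the same bases in another order gave a z as high. In oligodendrocyte-like cells limma gave a z of -0.47 (40 of 100 controls as high) and in RGL or astrocyte-like cells 0.13 (41 of 100). With 8-base matches only, z was -0.81, -0.98 and 0.18. The shift of seed-matched transcripts did not exceed that of the control motifs in any of the 3 comparisons.

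The share of each cell type among kept wells was compared between treatments. RGL or astrocyte-like cells made up 24.3% ± 8.92 in antagomir and 19.0% ± 1.94 in control mice (SD, n = 4 each; exact two-sided permutation p = 0.314, adjusted p = 0.947), and mouse 4 had the highest share with 36.7%. Oligodendrocyte-like cells made up 39.9% ± 10.5 and 44.5% ± 6.97 (exact p = 0.514), and neuroblast-like cells 4.54% ± 2.41 and 5.48% ± 1.67 (exact p = 0.600). Endothelial-like cells were at 11.6% ± 5.61 and 12.5% ± 7.02 (exact p = 0.8286), and mural-like cells at 12.1% ± 4.74 and 11.2% ± 3.18 (exact p = 0.771). No type differed beyond the spread between mice, where the smallest p that 4 against 4 mice allow is 0.0286. The sort gate set which cells could be counted.

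**Figure D4:**
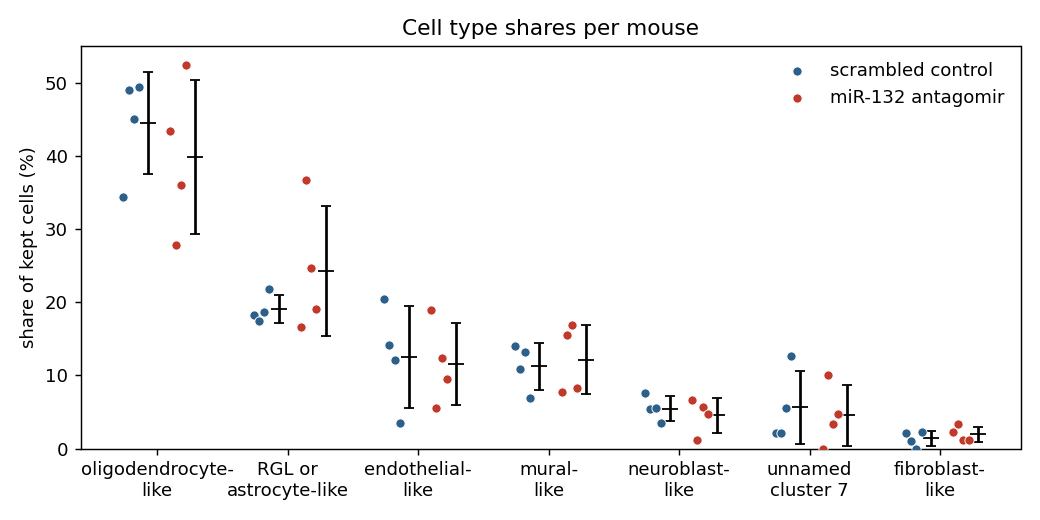
Share of kept wells of each cell type in percent, per mouse and treatment. Each point is a mouse and the black bar with whiskers is the mean ± SD over 4 mice; antagomir and scrambled mice overlap in every type, with RGL or astrocyte-like cells at 24.3% and 19.0%.

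Mitochondrial transcripts differed between the sequencing pools. Averaged over mice, the median share of mitochondrial counts per cell was 1.20% ± 0.169 in pool L5 and 4.12% ± 0.249 in pool L6 (SD, n = 4 each; exact permutation p = 0.0286). Every mouse of pool L6 lay above every mouse of pool L5, also within oligodendrocyte-like (1.16% and 3.72%), RGL or astrocyte-like (1.54% and 5.21%), endothelial-like (1.02% and 4.24%) and mural-like cells (0.936% and 3.05%). Between treatments the share was 2.65% ± 1.70 and 2.66% ± 1.70 (exact permutation p = 0.971). Both SDs hold the difference between pools, so this test could miss a small difference between treatments. Within sort day and pool, antagomir mice 4 and 6 lay above their scrambled partner and mice 2 and 8 below it.

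**Figure D5:**
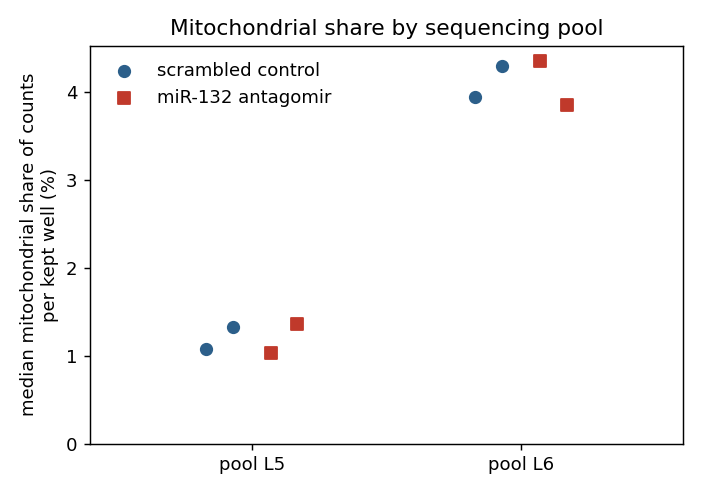
Median share of mitochondrial counts per cell in percent, per mouse, by sequencing pool and treatment. Each point is a mouse; the 4 mice of pool L5 lie at 1.36% or below and the 4 mice of pool L6 at 3.86% or above.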

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

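The tests on splits of the mice, the depth and Xist tests of the wells with many genes, the block of sort day and pool and the tests between treatments in those wells were chosen after the results were seen, and the matching on length and expression was first run with lengths of protein-coding transcripts alone and then repeated with all transcripts.

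The numbers of genes at an unadjusted p under 0.05 did not stand out among the 35 ways to divide the 8 mice into 4 and 4. In all cells 33 of the 35 splits gave as many genes as the real one (280 genes; highest other 1975). In oligodendrocyte-like cells 28 did (210 genes; highest other 1220), and in RGL or astrocyte-like cells 35 did (137 genes; highest other 504). Chance cannot be excluded for any of the 3 counts. The highest count came each time from the split by sequencing pool, several times the real count, which points to a structure of the samples by pool; that split called 24, 98 and 6 genes at an adjusted p of 0.05 by edgeR, where the real one called 0. Of the 8 splits that exchange treatments within sort day and pool, 7, 4 and 8 gave as many genes as the real one (highest other 453, 245 and 198). The split by sort day also gave more genes than the real one (445, 248 and 196). With sort day and pool as a block edgeR called 0 genes in each comparison, with 381, 301 and 173 genes at an unadjusted p under 0.05.

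The share of mitochondrial counts per cell was 3.44 times as high in pool L6 as in pool L5. A difference in cell types between the pools is argued against, since within oligodendrocyte-like cells alone the ratio was 3.22, with all 4 mice of pool L6 above all 4 of pool L5. The wells with over 6000 genes showed it too, with a ratio of 2.60, so a step of library preparation or sequencing of the pool may be the source. Base composition stays open: in oligodendrocyte-like cells nuclear genes of like GC content differed between pools by 0.65 on the log2 scale, 45.4% of the 1.43 of the mitochondrial genes, between the bounds set for a cause and for none. The second sort day had 1.28 times the share of the first in pool L5 and 0.98 times in pool L6, and the design names no biological difference between the pools, so none was tested.

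The 16 wells left out for over 6000 detected genes had a median of 11152.5 genes, where kept wells had at most 5625. They were 2 per mouse, in plate rows I and J and columns 4, 9, 16 and 21. The median such well held at least 3 markers of 5 of 5 cell classes, which may mean that many sorted cells were placed together in 1 well. Deeper sequencing of single cells is argued against, because their median total was 1.55 times that of kept wells, where more than 3 times was required, and a control RNA from females or from both sexes is argued against because 0 of the wells had over 3 counts of Xist. With these wells summed per mouse, edgeR called 0 of 10844 genes, with 118 higher and 126 lower at an unadjusted p under 0.05.

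The 3 gene lists that passed by camera with a preset correlation in the kept cells were tested on the same splits. Oxidative phosphorylation in oligodendrocyte-like cells had a camera p of 5.8e-05, and 4 of 35 splits gave one as small (smallest other 7.38e-07). Ribosomal proteins had a p of 0.000198, with 5 of 35 as small (smallest other 5.04e-10), and myelin genes in all cells a p of 0.000144, with 9 of 35 as small (smallest other 2.39e-13). Among the 8 splits that exchange treatments within sort day and pool, the real p was the smallest for oxidative phosphorylation (smallest other 0.00629) and ribosomal proteins (0.00191), and 3 of 8 were as small for myelin genes (smallest other 1.85e-09); 8 splits are too few to exclude chance. Chance cannot be excluded for any of these lists, and an effect of the antagomir stays open as well. The mean log2 difference of oxidative phosphorylation lay at the 99.8th percentile of 10000 random lists matched on transcript length and expression. Genes of the random lists were drawn independently, whereas those of this list had an estimated correlation of 0.18. The percentile thus cannot decide whether short and abundant transcripts alone account for this list. For ribosomal proteins the mean lay at percentile 87.37, so length and expression may account for it.

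A single mouse stood apart from the other 3 of its treatment in 16 of 201 groups tested (7.96%), where chance gives about 1 in 20 for continuous values. For Parp10, Ubxn11, Hsf5, P4ha3 and Ntng2 the other 3 mice were at 0, so any count in the remaining mouse was flagged. The rate of 1 in 20 does not apply to these genes. Mouse 8 had 84 kept wells against 89 to 90. On the log2(CPM + 1) scale in all cells, Parp10 was at 0.0324 in mouse 6 against 0 in the other antagomir mice, Nusap1 at 0.778 in mouse 1 and Tubb3 at 7.38 in mouse 5. In oligodendrocyte-like cells the values were 0.113 for Ubxn11 in mouse 5, 7.47 for Phf5a in mouse 8, 2.73 for Tmem169 in mouse 7, 0.0803 for Hsf5 in mouse 6 and 8.22 for Rps9 in mouse 8. In RGL or astrocyte-like cells they were 6.23 for Suox in mouse 2, 7.13 for Hipk2 in mouse 4, 0.289 for P4ha3 in mouse 4, 0.147 for Ntng2 in mouse 8, 5.75 for Arhgap32 in mouse 6, 15.4 for Apoe in mouse 8 and 0 for Hmgb2 in mouse 8.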

How the results depend on the processing

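The fits with sort day and pool as a block, with pool as a covariate, without mitochondrial reads, with all wells or with the unnamed cluster were chosen after seeing the data; the others of this part were planned. No paired analysis was possible on the titles' replicate numbers because the wells could not be tied to the samples that carry them; on sort day and pool the antagomir mouse correlated best with its own partner in 1, 1 and 3 of 4 pairs, and this block changed no call by edgeR or camera. Fry's call of disease-associated microglia in oligodendrocyte-like cells was lost with it (adjusted p = 0.433) and without any mouse but mouse 2 (0.0447; the others 0.0605 to 0.559). The count of genes stayed at 0 by edgeR under every other setting run, each left-out mouse included, and by limma; DESeq2's Wald test called 10, 14 and 7. Without a mouse, genes at an unadjusted p under 0.05 ranged from 349 to 530, 243 to 413 and 221 to 307. By limma on mean log2 values per cell the median of all genes in RGL or astrocyte-like cells was -0.18. Simulated 4-fold changes were recovered for 59%, 43% and 5% of the changed genes, all of which averaged over 20 CPM.

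Nacc2 ranged from -0.44 to -0.06, from -0.76 to -0.26 and from -0.11 to 0.35 in all, oligodendrocyte-like and RGL or astrocyte-like cells without a mouse, and the difference between types from 0.34 to 1.07; in RGL or astrocyte-like cells it turned to -0.11 without mouse 8. In oligodendrocyte-like cells it was -1.26 by limma on mean log2 values (unadjusted p = 0.0234, adjusted p = 0.999). Of 1543 refits of the named genes other than Nacc2 1535 kept the sign, and 45 of 88 log2 differences moved by over 1.5 times without a mouse. The exceptions were Ccne1 at -0.0066 (limma) and -1.36 (pool), Cd63 at -0.23 (limma), Lpl at 0.0099 (limma), 0.22 (block) and 0.0378 (pool), Sox2 (-0.31 to 1.08 without a mouse, negative without mouse 4) and Cd63 (-0.0319 to 0.31, negative without mouse 8). The cause was not tested. These genes were picked by their small p in the same mice that were refitted, so a kept sign was nearly fixed in advance. Refits in which a gene failed the filter were not counted.

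The list of myelin genes had adjusted p-values of 0.868 with an estimated correlation, 0.925 by fry and 7.27e-07 to 0.205 without a mouse (lost without mouse 3, 4, 6 or 7). Oxidative phosphorylation had 0.510, 0.502 and 3.3e-05 to 0.0529 (lost without mouse 8), and ribosomal proteins 0.510, 0.502 and 6.41e-05 to 0.0721 (lost without mouse 4). Lists past the threshold were 0 by either test in all cells (0 to 4 without a mouse), 0 and 1 in oligodendrocyte-like cells (1 to 4) and 0 in RGL or astrocyte-like cells (0 to 2). Matching on 3' UTR length and expression gave seed-matched genes mean log2 differences of 0.0016, -0.014 and -0.018, of which all cells and RGL or astrocyte-like cells took the other sign.

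Differences in share kept their sign except mural-like cells at -0.0139 points with at least 1000 genes per cell and, without a mouse, mural-like (-0.677 to 2.35; mouse 4, 6 or 7), endothelial-like (-3.97 to 1.69; mouse 1 or 4), neuroblast-like (-1.65 to 0.206; mouse 4), oligodendrocyte precursor-like (-0.269 to 1.21; mouse 2) and unnamed cells (-2.90 to 1.26; mouse 2 or 7); RGL or astrocyte-like, oligodendrocyte-like and fibroblast-like cells ranged from 1.10 to 7.76, -8.76 to -0.561 and 0.122 to 0.888. Leiden resolution 0.5 gave no neuroblast-like or oligodendrocyte precursor-like cluster, and a minimum of 20 cells left RGL or astrocyte-like cells untested.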

Other observations

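The tests in this part, and the genes named in it, were all chosen after the data had been examined.

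Endothelial-like and mural-like cells were tested between treatments although some mice had few of them (at least 3 and 6 cells). By edgeR 0 of 6448 genes passed in endothelial-like cells, with 11 higher and 21 lower at an unadjusted p under 0.05, and 0 of 6795 in mural-like cells, with 26 and 37; no other tool was run.

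Oligodendrocyte-like cells of pool L6 differed from those of pool L5 in 98 genes by edgeR, 47 higher and 51 lower. Higher in pool L6 were mt-Rnr2, the mitochondrial large ribosomal RNA, by 1.66 on the log2 scale (SE 0.088, adjusted p = 3.18e-05), the nuclear long noncoding RNA Malat1 by 2.02 (SE 0.11), the oligodendrocyte lineage factor Olig2 by 1.79 and the endosomal GTPase Rab5a by 2.49. Lower were Mag, a myelin adhesion protein, at -0.86, Serinc5, a serine incorporator, at -1.38, and Cntn2, an adhesion molecule of myelinated axons, at -1.14. In RGL or astrocyte-like cells 6 genes were higher in pool L6, 5 of them mitochondrial and the other Malat1, and none was lower. Over 10525 nuclear genes in oligodendrocyte-like cells the log2 difference, L6 minus L5, fell with GC content and turned negative. The Spearman correlation was -0.28, across genes, which are not independent replicates. The median difference was 0.65 for genes with GC content like that of the mitochondrial genes and -0.28 for genes above 57.3% GC.

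In the wells with over 6000 genes, lists were tested between treatments with 2 wells per mouse. All such wells of scrambled mice lay in plate row I and all of antagomir mice in row J. Plate row and treatment cannot be told apart here. The wells differed in the markers they held, with 1 to 10 mural and 0 to 9 neuroblast markers at 10 counts or more per well. Mural cell and vascular matrix genes fell by camera with a preset correlation (18 of 19 negative, median -0.53, adjusted p = 2.65e-07; 0.794 with an estimated correlation). Genes of neuronal differentiation rose (14 of 19 positive, median 0.36, adjusted p = 0.000982; 0.794 with an estimated correlation), as did those of quiescence (21 of 25, median 0.39, adjusted p = 0.0409; 0.948), and myelin genes fell (17 of 18 negative, median -0.20, adjusted p = 0.0188; 0.948). No gene of these 4 lists passed when adjusted over the list alone. Nacc2 was at 99.2 ± 33.9 CPM in antagomir and 74.0 ± 21.6 in control mice (SD, n = 4 each; edgeR adjusted p = 1.00).

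In the small cluster of 23 RGL or astrocyte-like cells with Nes in all of its cells, Nacc2 was detected in 7 of 9 antagomir and 5 of 14 control cells. Per mouse this was 83.3% ± 28.9 (SD, n = 3) and 42.0% ± 42.5 (n = 4; exact permutation p = 0.229). Mouse 2 had 0 cells in this cluster.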
